A study of Rattus with 6 samples.

How the data were processed

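Blood plasma RNA of rats was profiled on a 1-colour circRNA microarray. The samples fall into groups of 3 that the labels call 0 h and 2 h; the labels use MIRI, for myocardial ischaemia-reperfusion injury, for both. Per the labels' protocols, the coronary artery was tied for 40 min, blood was taken after 2 h of reperfusion, and sham-operated rats had the thread placed but not tied. The labels speak of 6 male rats in an injured and a sham-operated group without saying outright that the 0 h samples are the sham-operated rats, so the groups are named 0 h and 2 h here. Also per the labels' protocols, total RNA was digested with RNase R, an exonuclease that degrades linear RNA, and the rest was labelled with Cy3 by random priming.

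The deposited scanner files hold spot intensity on a linear scale, and per the file headers they were made with Agilent Feature Extraction 11.0.1.1, which subtracted the background from the processed signal and did no scaling between arrays. Other columns used here, per the file headers, were the median spot and local background intensity, the SD of the background pixels, and the scanner software's flags. Each array has 15701 spots. They include 14145 circRNA probes with 1 spot each, 62 probes for linear transcripts with 10 spots each, 20 custom probes without a name with 20 spots each, and control spots. The authors' deposited value table is on a log2 scale and covers the circRNA probes. Its columns followed quantile-normalized log2 median spot intensity without background subtraction (r from 0.997 to 0.998 across probes), but were not reproduced exactly. The SD of the difference was 0.126 to 0.135, so that the background was left in is inferred only. Column medians lay between 5.41 and 5.43, without centring at 0. The submitters' processing notes name limma, and the version and steps are not given in the sources used here.

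Control spots and spots that the scanner software called outliers were left out, the log2 processed signal was averaged over the spots of a probe, and the 75th percentile of all non-control probes was subtracted on each array. On average 81.2% of non-control probe values were well above background by the scanner software's flag, and no spot was saturated (0 spots). A probe was tested if it was well above background on at least 3 of the 6 arrays, which kept 11656 circRNA probes (82.4%) and 41 linear-transcript probes. The groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the circRNA probes, and separately over the linear-transcript probes, at a threshold of 0.05. A looser screen took probes at an unadjusted p under 0.05 that differed by at least 1.5-fold. A fold is the ratio of group means on the log2 scale; for a probe that was well above background on none of the arrays of a group, only a lower bound of the fold is given, taken against the higher of the dim probe's signal and the lowest signal among detected probes per array.

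The test was checked on simulated data for 11635 circRNA probes, of which 200 were changed. Each probe kept its real spread between arrays, but noise was drawn independently for each probe. Deviations that probes share on a real array were left out, so the rates below may not hold for the real arrays. Of probes changed 1.5-fold, 2-fold and 4-fold, the adjusted test called 26.9%, 64.2% and 90.9%, and the screen took 50.7%, 95.5% and 98.5%. Of the unchanged probes, 10 passed the adjusted test and 131 the screen. The number of arrays limits the precision.

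The comparison of circRNA probes and its tests, 23 gene lists and most alternatives were fixed before the data were examined; normexp on the median spot signal, the background added back, all fits on linear-transcript probes and most tests of explanations were chosen afterwards. The rule for named circRNA probes took 12 per direction past the adjusted test with no overlap between the groups, filled up with those of smallest unadjusted p among probes at least 1.5-fold different without overlap. The files and the reference table used here do not pair circRNA probe IDs with genes or positions, so the first 2 IDs of each direction are printed, no gene is given for them, and the planned tests of host gene lists and of circRNA classes were void (0 circRNA probes with a host gene). The linear-transcript probes carry transcript accessions; 39 of the 62 matched a symbol in a RefSeq gene table of assembly GRCr8, and 23 did not. Their comparison, and the choice of which to name, were made after the files had been seen: named are the genes at an unadjusted p under 0.05, members of the fixed lists, and reference genes.

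Alternatives were quantile normalization, median scaling, another set of probes behind the percentile, normexp on the median spot signal with an offset of 50 (the planned mean signal column was not used here), the median background added back to the processed signal, no or a stricter filter on dim probes, the replicate number as a block, trended robust eBayes, array weights, the authors' values, and leaving out each array. The arrays were read in 1 scan of 1 slide, where the position codes put the 0 h arrays in one row and the 2 h arrays in the other, so slide row and group cannot be told apart and no fit with the row as a block was possible.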

Results

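Circular RNAs in blood plasma were compared between samples labelled 0 h and 2 h in a rat study of myocardial ischaemia-reperfusion injury, in which a coronary artery is closed and reopened. There were 3 arrays per group, each with 14145 circRNA probes, single spots against back-splice products that have no free ends and resist the exonuclease RNase R. The comparison asks which plasma circRNAs differ with this injury, though the labels leave open how the 0 h rats were treated. Between 10813 and 12523 circRNA probes were well above background per array, with a mean of 11298 ± 353 at 0 h and 11709 ± 858 at 2 h (SD, n = 3 each). The difference of 412 probes had an exact permutation p of 0.6, two-sided, where the smallest possible value was 0.1; leaving out an array moved it to between 4.83 (without 2 h replicate 2) and 860 (without 2 h replicate 1). By a flag for signals above the local background plus 2 SD of its pixels, the difference was 783 probes, with an exact permutation p of 0.1, two-sided, the smallest possible. Signals were dim: the median circRNA probe read 16.7 to 24.6 scanner units after background subtraction, over a local background of 17 to 19. Across circRNA probes, arrays correlated at r of 0.984 to 0.988 within the 0 h group, 0.981 to 0.990 within the 2 h group and 0.973 to 0.986 between groups. The first principal component held 42.6% of the variance, and on it the 2 h arrays scored -2.73, 31.2 and 14.7 against -9.29, -8.01 and -25.9 at 0 h.

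Among the plasma circRNA probes that differed most, more were higher than lower at 2 h, but none passed the adjusted test. The median log2 difference over all tested probes was -0.0045, which the scaling of each array holds near 0. In the screen, 560 of the 11656 tested circRNA probes differed by at least 1.5-fold at an unadjusted p under 0.05 (limma), 474 of them higher at 2 h and 86 lower, so that 84.6% were higher. Such a share was not unusual: of the other groupings of the same 6 arrays into 3 and 3, 5 were more one-sided, at up to 99.4%, though each screened fewer probes (at most 312). The median fold was 1.76 among the higher probes, and 1.64 as 0 h over 2 h among the lower ones. At least 2-fold differences were seen for 130 higher and 13 lower probes, and at least 4-fold for 2 higher and 0 lower. With quantile normalization 66.1% of 555 screened probes were higher (367 higher, 188 lower), and with median scaling 72.1% of 555 (400 higher, 155 lower). The array of 2 h replicate 2 had the highest value of its group in 415 of the 474 higher probes (87.6%), against 42.2% of all tested probes; without it the screen took 278 higher and 140 lower, and without 2 h replicate 1 it took 784 and 82. Without 0 h replicate 2 it took 505 and 164, and without 0 h replicate 3 it took 417 and 138. Background treatment and the filter changed its size and balance too. It took 868 probes without a filter on dim probes (764 higher, 104 lower), 152 with the background added back (107 higher, 45 lower) and 109 with the authors' deposited values (80 higher, 29 lower). With normexp correction it took 72, of which 39 were higher and 33 lower (54.2% higher).

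After Benjamini-Hochberg adjustment in limma, 0 of 11656 circRNA probes passed, with a smallest adjusted p of 0.178. At an unadjusted p under 0.05 there were 1500 probes (1051 higher, 449 lower), where 583 would be met by chance if probes were independent; other groupings of the same 6 arrays into 3 and 3 gave up to 1083. Leaving out an array moved the count to between 971 (without 2 h replicate 2) and 2054 (without 2 h replicate 1). The groups did not overlap for 2252 probes (19.4%), where 10% is the mean over all groupings of the arrays into 3 and 3. Probes share deviations, so a single grouping can lie well off that mean. The share in the other groupings was not computed, so the excess cannot be judged. The adjusted count depended on the spread model and the background: trended robust eBayes in limma called 48 probes, all 48 higher at 2 h, and 47 of them were in the screen. With the background added back, a setting chosen after the data had been seen, 140 probes passed (122 higher, 18 lower), and all 48 of the previous setting were among them. Normexp background correction gave 12 (9 higher, 3 lower), and the filter for probes above background on all arrays and the authors' deposited values gave 1 each. The other settings tried, and leaving out any array, gave 0.

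**Figure D1:**
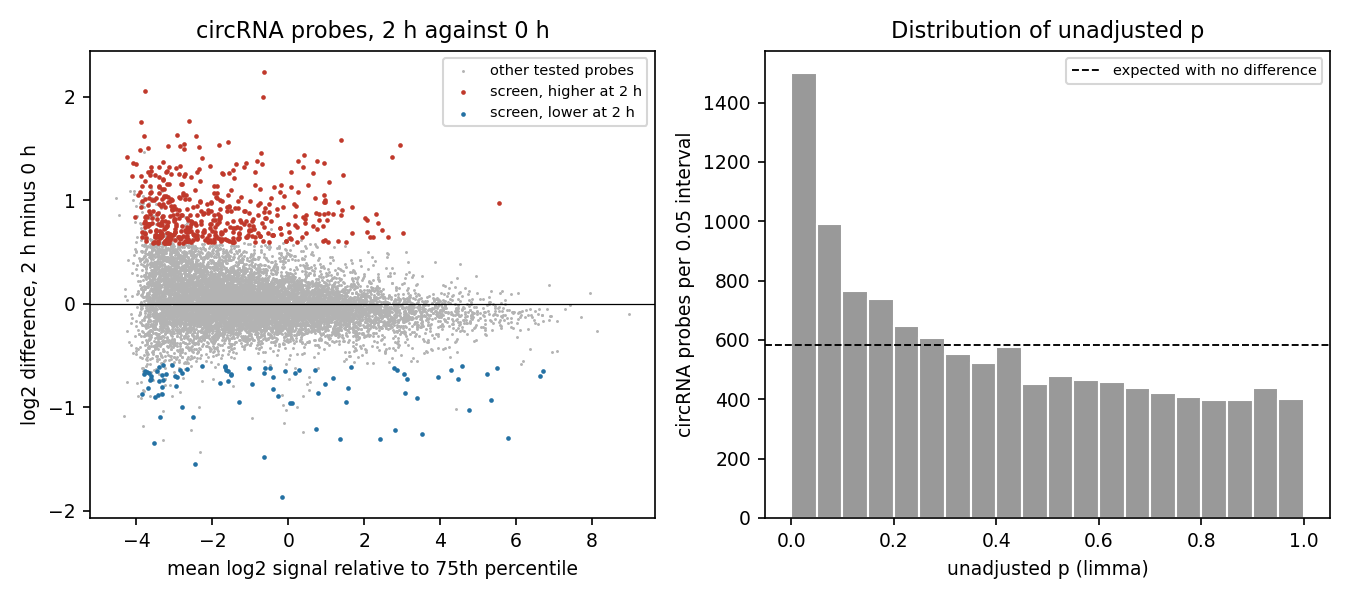
Left, log2 difference (2 h minus 0 h) of each tested circRNA probe against its mean log2 signal relative to the 75th percentile of the array, with screened probes in red (474 higher at 2 h) and blue (86 lower). Right, number of circRNA probes per 0.05 interval of unadjusted limma p, with the number expected with no difference as a dashed line; the lowest interval holds 1500 probes against 583.

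Among the circRNA probes that the naming rule took, none past the adjusted test, the 12 higher ones had log2 differences of 0.82 to 2.24 and the 12 lower ones of -1.55 to -0.65. The files and tables used here do not pair these IDs with genes. Probe ASCRPR007498 was 2.05-fold higher at 2 h (log2 difference 1.04 ± 0.10 SE, n = 3 per group; adjusted p 0.178, limma with Benjamini-Hochberg), with a geometric mean signal of 41.2 at 0 h and 84.6 at 2 h. ASCRPR012940 was 1.89-fold higher (log2 difference 0.92 ± 0.11 SE; adjusted p 0.185, limma with Benjamini-Hochberg), from a signal of 5.61 with 2 of 3 arrays above background to 10.6. ASCRPR012429 had a log2 difference of -0.88 ± 0.14 SE (adjusted p 0.185, limma with Benjamini-Hochberg), with signals of 8.64 at 0 h and 4.71 at 2 h, where 2 of 3 arrays were above background. ASCRPR001489 read 6.71 at 0 h and was not well above background on any of the 3 arrays at 2 h, so it was at least 1.43-fold lower (adjusted p 0.185, limma with Benjamini-Hochberg). The log2 differences of the other 3 probes were smaller in other treatments of the background. Under normexp correction the log2 differences were 0.53 for ASCRPR007498 and 0.21 for ASCRPR012940, and turned to 0.048 for ASCRPR012429. With the authors' deposited values they were 0.74, 0.18 and -0.18 in the same order; ASCRPR001489 has only a bound.

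Screened probes were more frequent among dim ones. In 4 bins of equal size by mean signal, with median signals of 7.55, 18.4, 46.7 and 192, the screen took 8.89%, 4.43%, 3.19% and 2.71% of circRNA probes. Higher and lower probes numbered 227 and 32 in the dimmest bin, 119 and 10, 78 and 15 in the middle ones, and 50 and 29 in the brightest. The median residual SD between arrays was 0.31, 0.18, 0.14 and 0.13 on the log2 scale, from the dimmest bin to the brightest. Of the 474 higher probes, 34 were not well above background on any 0 h array, and of the 86 lower probes 6 were not on any 2 h array.

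The array also carries probes for linear messenger RNAs, which were examined after the files had been seen. Whether their signal came from linear RNA left after RNase R digestion was not tested. Map2, of the list kept as a neuron control, read 34.9 at 0 h, brighter than either Ldha probe. The largest difference among the linear probes was in Ldha, which encodes the A subunit of lactate dehydrogenase. Both Ldha probes read higher at 2 h without overlap between the groups, one 2.71-fold (log2 difference 1.44 ± 0.34 SE, n = 3 per group; signal 8.81 to 23.9) and the other 2.09-fold (1.07 ± 0.37 SE; signal 6.75 to 14.1). The other probe's groups were only narrowly apart, with scaled log2 signals of -2.80 on 2 h replicate 1 and -2.84 on 0 h replicate 2. Their adjusted p was 0.0949 and 0.108 (limma with Benjamini-Hochberg over 41 linear probes). Pdcd10, an adaptor protein gene mutated in cerebral cavernous malformation, read 1.67-fold higher (0.74 ± 0.19 SE; adjusted p 0.0949, limma with Benjamini-Hochberg). Slc28a2, a sodium-coupled purine nucleoside transporter, read 1.58-fold higher (0.66 ± 0.20 SE), and Nlrp3, the inflammasome sensor, 1.46-fold higher (0.55 ± 0.17 SE), though above background on 1 of 3 arrays at 0 h and 2 of 3 at 2 h. Hprt1, a purine salvage enzyme, read 1.26-fold and Gusb, the lysosomal beta-glucuronidase, 1.24-fold higher; for these 4 genes the adjusted p was 0.108 (limma with Benjamini-Hochberg). Rplp1, a ribosomal stalk protein gene, read 2.01-fold higher, with overlapping groups, 1 of 3 arrays above background at 0 h, and an adjusted p of 0.147 (limma with Benjamini-Hochberg).

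For several reference and list genes the difference was smaller than its SE. The probes of Pgk1, Actb, Rpl13a, Sdha and Hsp90ab1 share an ID series. The same series holds the first Ldha probe, Rplp1, Hprt1 and Gusb, which read higher at 2 h, and B2m, which read lower. The log2 difference was 0.00 (-0.0013) ± 0.09 SE for Pgk1, a glycolytic enzyme, 0.03 ± 0.13 SE for Actb, 0.07 ± 0.16 SE for Rpl13a and -0.04 ± 0.11 SE for Sdha of mitochondrial complex II. It was -0.09 ± 0.10 SE for the chaperone gene Hsp90ab1, the brightest linear probe at 1572 units at 0 h and 1477 at 2 h. Larger differences, at an unadjusted p above 0.05, were -0.32 ± 0.18 SE for B2m, the light chain of MHC class I, and 0.42 ± 0.25 SE for Eif4b, a translation initiation factor above background on 1 of 3 arrays at 0 h and 2 of 3 at 2 h. Among probes without a symbol, the largest log2 difference was 1.09 ± 0.27 SE (adjusted p 0.0949, limma with Benjamini-Hochberg). Another probe had -0.27 ± 0.09 SE, the only lower linear probe at an unadjusted p under 0.05 in limma. Further ones had 0.32 ± 0.11 SE (unadjusted p 0.022, limma) and 0.53 ± 0.25 SE (unadjusted p 0.079, limma, with overlapping groups). The median over the 41 tested probes was 0.03, and camera against the circRNA probes gave a p of 0.0964 with a preset correlation and 0.538 with an estimated correlation.

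Of the 41 linear probes, 0 passed the adjusted test in limma (smallest adjusted p 0.0949), 11 had an unadjusted p under 0.05 (10 higher, 1 lower) where 2.05 would be met by chance if probes were independent and other groupings of the arrays gave up to 4, and 6 passed the screen, all higher. With quantile normalization, median scaling or array weights 3 passed the adjusted test, in each case an Ldha probe, Pdcd10 and a probe without a symbol, ENSRNOT00000072358, which read 2.13-fold higher. With the background added back 7 passed, among them both Ldha probes, Pdcd10, Slc28a2 and Rplp1. Without 2 h replicate 1, 10 passed, and without 2 h replicate 2 only an Ldha probe did. Over the 16 alternatives run on it, the first Ldha probe read 1.28-fold to 3.34-fold higher, with an adjusted p (limma with Benjamini-Hochberg) from 3.9e-05 to 0.316. The other Ldha probe read 1.19-fold to 2.59-fold higher, with an unadjusted p under 0.05 in 13 of 16. Over the alternatives run on each, Pdcd10 read 1.15-fold to 1.91-fold, Slc28a2 1.15-fold to 1.81-fold and Nlrp3 1.12-fold to 1.61-fold higher, with an unadjusted p under 0.05 in 16 of 16, 15 of 16 and 11 of 15. The range was 1.1-fold to 1.34-fold for Hprt1, 1.1-fold to 1.31-fold for Gusb and 1.16-fold to 2.60-fold for Rplp1, with an unadjusted p under 0.05 in 11 of 16, 8 of 16 and 8 of 15. These genes were named for their unadjusted p in the main fit, and the alternatives reuse the same arrays.

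**Figure D2:**
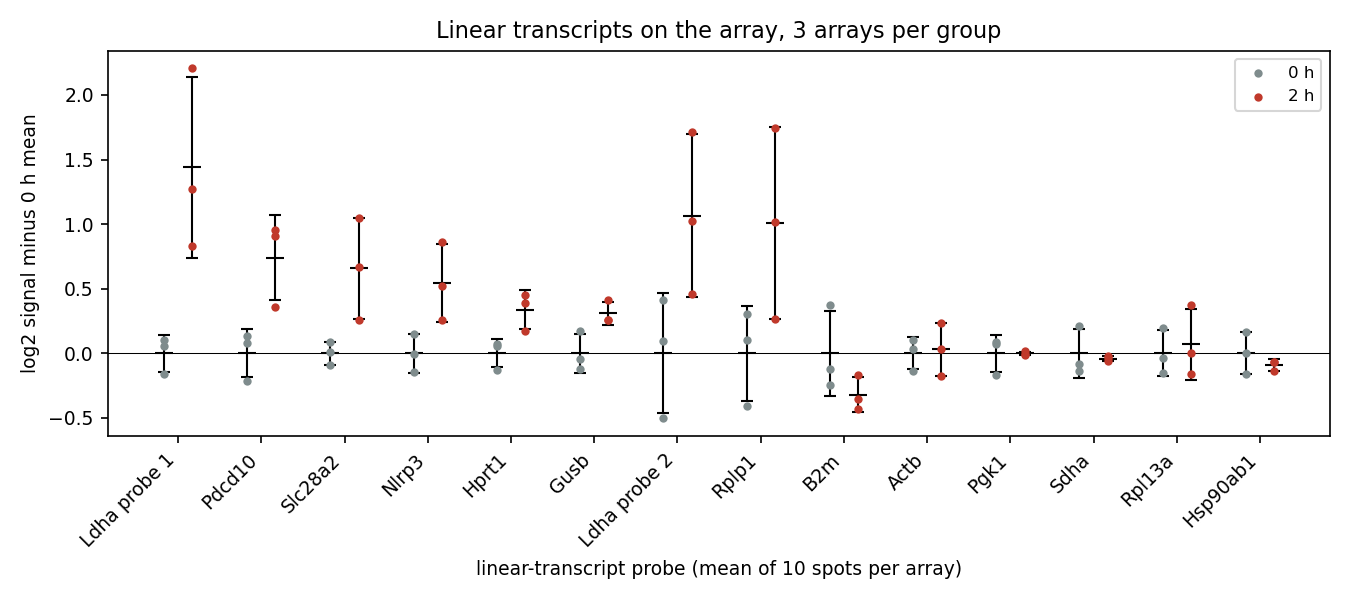
Log2 signal of linear-transcript probes on each array, minus the mean of the 0 h arrays; grey points are the 3 arrays at 0 h, red points the 3 at 2 h, and the dash and bar are the group mean and SD. The 2 h arrays of both Ldha probes lie above all 0 h arrays, though narrowly for the second, with means 1.44 and 1.07 above them, whereas Pgk1, Actb and Sdha lie near 0.

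Of the 23 gene lists fixed in advance, 6 had a tested linear probe and 0 had the 5 probes needed for a set test. The hypoxia list had 3, the Ldha probes and Pgk1. Of these, 2 passed when adjusted over the list alone, both for the 1 gene Ldha, and 0 over all linear probes tested (limma with Benjamini-Hochberg). The inflammation list had Nlrp3 alone (1 passed adjusted over the list alone, which with 1 member is the unadjusted test, and 0 over all). The mitochondrial list had Sdha, the heat shock list Hsp90ab1, the hepatocyte list Cyp2e1, a liver cytochrome P450 (log2 difference 0.03 ± 0.12 SE), and the neuron list, kept as a control, Map2 (-0.14 ± 0.12 SE), with 0 passing either way. The remaining lists, among them those of cardiomyocytes, red cells, platelets, leukocytes and endothelium, had 0 tested linear probes.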

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

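Normexp, the background added back and every fit on linear probes were chosen after the data had been seen; the rest was planned. The circRNA count past the adjusted test, 0, became 12 with normexp, 140 with background added back, 48 with trended robust eBayes, 1 with the all-array filter and 1 with the authors' values. It stayed 0 under quantile, median and other-percentile scaling, without a filter, with array weights and without any array. The screen count of 560 became 72 with normexp, 152 with background added back, 868 without a filter (14145 tested) and 109 with the authors' values. It ranged from 418 (without 2 h replicate 2) to 866 (without 2 h replicate 1), and 389 to 617 elsewhere. Of the 560 probes, 530 kept their sign with normexp and 552 with the authors' values. With the replicate number as a block, the adjusted count was 0 for circRNA and linear probes and the screen counted 580; samples share only a number (deviations of same-numbered arrays correlated at -0.115, 0.019 and -0.068, and 0 of 6 arrays correlated best with their own number). For linear probes, the adjusted count of 0 became 7 with background added back and 3 each with quantile normalization, median scaling and array weights, and 0 to 10 without an array. Their screen count of 6 became 1 with normexp and 2 with background added back. The log2 differences of ASCRPR012429 and ASCRPR001489 turned to 0.048 and 0.087 with normexp; the latter was not well above background on any of the 3 arrays at 2 h, so its sign is not measured there. Of 191 refits of named probes 158 kept direction and side of an unadjusted 0.05, 31 kept direction only and 2 reversed. The named probes and the 560 were picked by the main fit on the same arrays, so keeping the direction was likely in any case. The difference in detected probes was 783 by a flag on background SD (exact permutation p 0.1, the smallest possible) and 4.83 to 860 without an array. Low signal over background limits dim probes; where no cause is given, the cause was not tested. A slide block and host gene tests were not run.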

Other observations

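The tests below were chosen after the results were seen, except that of dim probes. For background left in the authors' values the prediction was written beforehand, but the fit it uses was chosen after the data had been seen. The spread between spots and the control probes were looked at without a prediction.

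Replicate spots give a measure of noise within an array. For linear-transcript probes with a signal under 10, the SD between spots on an array was 0.24 on the log2 scale, and it was 0.15 for signals of 10 to 30 and 0.07 above 30. Single-spot circRNA probes in the same ranges had median SDs between arrays of a group of 0.33, 0.18 and 0.13, and linear-transcript probes, averaged over 10 spots, of 0.25, 0.13 and 0.12. Among 80 control and unnamed probes, 0 were at least 1.5-fold higher at 2 h with no overlap between the groups.

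The first pattern is the excess of circRNA probes that were higher at 2 h in the screen. Without 2 h replicate 2, 66.5% of screened probes were still higher; quantile normalization left 66.1%, tested probes of above-median signal 71.2%, normexp correction 54.2% (39 higher, 33 lower) and the background added back 70.4%, so background treatment stays open as a source. None of these fell to 50%, but other splits of the arrays reached 99.7% and 80.5% in the first and second of these fits. That array and the scaling by a single percentile may therefore each account for part of the excess. So may dim probes, since other splits screened at most 42 bright probes (as few as 1) against 184 in the real split. These are too few to set their percentages beside it. The 184 differ from the main screen in bins 3 and 4 by signal, with 78 higher and 15 lower, and 50 higher and 29 lower. The 3 against 3 arrays make 10 splits, too few for a share under 0.05; the real split's 84.6% was exceeded by 5 others (up to 99.4%), but it alone (1 of 10) gave 474 probes in its larger direction, against at most 310 in another, and likewise for the whole screen (1 of 10), with 560 against at most 312. Slide row and a difference between the groups in plasma circRNA stay open, the latter untested.

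At an unadjusted p under 0.05 the real split gave 1500 circRNA probes and another split up to 1083. For the adjusted count of 0 the splits decide nothing, since any split gives at least 0 calls (10 of 10 did; the highest other was 1 for circRNA probes and 0 for linear probes). With trended robust eBayes the real split gave 48 circRNA probes against at most 8 in another split, and with the background added back 140 against at most 8; 10 splits are too few for a share under 0.05.

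The second pattern is the higher Ldha and some other linear transcripts at 2 h. In all 8 named higher probes, 2 h replicate 2 read highest of its group, then replicate 3, then replicate 1. The 2 h arrays had the same order on the first principal component of the circRNA probes. They also had it in the 75th percentile of signal (74.7, 65.1 and 56.2) and in circRNA probes above background (12523, 11792 and 10813). At 0 h the 75th percentile was 65.4, 59.7 and 66.3 for replicates 1 to 3, so the groups overlapped in it. Whether array brightness or background raised these probes was not tested. The genes share 1 order of arrays and are therefore not separate lines of evidence. Less complete digestion of all linear RNA at 2 h would raise linear probes alike. Their median log2 difference was 0.026 (bootstrap 95% interval -0.04 to 0.25, 10000 resamples of the probes), below the 0.63 that 50% of the mean Ldha difference comes to. The interval leaves out the variation between arrays, so it understates the uncertainty of the group difference. Ldha was picked as the largest difference among these probes, so a median below that mark was likely in any case. The test therefore cannot decide, and both a smaller uniform change and digestion that differs between transcripts stay open. Without 2 h replicate 2 the Ldha log2 differences were 1.05 for the first probe and 0.74 for the other, and the groups did not overlap. For the other probe the gap was narrow. Its scaled log2 signal was -2.80 on 2 h replicate 1 and -2.84 on 0 h replicate 2, with unscaled signals of 8.10 and 8.33. The values argue against 2 h replicate 2 as the sole source for the first Ldha probe, and the other adds little. The 2 slide rows hold 1 group each (0 rows hold both), so slide row and group cannot be told apart, and the real split was the 1 of 10 with 6 screened linear probes, against at most 2, again too few splits for a share under 0.05. A hypothesis is that plasma at 2 h may hold more of certain linear transcripts; which cells they come from was not tested.

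The third pattern is the smaller screen with the authors' values, 109 probes against 560. Adding the median background of each array to the processed signal gave 152, within 1.5 times of the authors' count. The match held for the screen only, since 140 circRNA probes passed the adjusted test in that fit against 1 with the authors' values. Quantile normalization of the processed signal gave 555 screened probes, which argues against that step as the source. Among screened probes, the log2 difference in the authors' values was a median 0.167 of that from processed signals in the dimmest of 4 bins of tested probes, then 0.403, 0.647 and 0.876 in the brighter bins. Background left in the authors' values is a candidate explanation for the smaller differences of dim probes.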
